A study of Mus musculus with 9 samples.

How the data were processed

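RNA-seq was used to profile substantia nigra lysate from wild type C57BL/6 mice that had undergone a sham operation. The substantia nigra is the midbrain region that contains the dopaminergic neurons lost in Parkinson's disease. Per the labels' protocols, mice entered the study at 12 weeks of age, a fast lasted 24 hours and began 2 hours before lights off, and the intermittent regimen had 3 fasts per week. Mice on the ad libitum diet were moved between cages on the same schedule. The 9 libraries fall into 3 groups of 3 by their treatment label: ad libitum for 1 week, fasted for 1 day, and 1 week of intermittent fasting. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries, part of which can be technical. The interval between the end of the last fast and sampling is not given in the sources used here.

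Per the labels' protocols, total RNA was extracted with the RNeasy Lipid Tissue Mini kit, polyA RNA was used and libraries were made with the directional NEBNext Ultra II kit, which keeps the strand. The submitters' processing notes name Salmon, which estimates read counts per transcript, DESeq2 1.40.2 and the mouse builds GRCm39 and mm39. The version of Salmon, the annotation release, the step from transcripts to genes and the filter on rows are not given in the sources used here. The deposited table holds estimated counts per gene and library as whole numbers that are not scaled to depth, so no rounding was needed. It has 20591 rows, and the lowest mean of any row is 9.89 counts per library. Genes below about that level are therefore not analysed here. Library totals ranged from 36109995 to 54248856 counts. No pair of libraries matched within sampling noise, since the lowest chi-square per gene of any pair was 26.5. Salmon divides reads between near-identical transcripts, so the counts of pseudogenes and of close paralogs are uncertain. No genomic coordinates are printed, because the annotation at hand was of another build (GRCm38) and was used for transcript length and GC content alone, by gene identifier.

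Genes were tested with edgeR 4.0.16 in R 4.3.3. Counts were scaled by TMM factors, filterByExpr (minimum count 10, minimum total count 15) removed 56 rows and left 20535 genes, and a quasi-likelihood model with robust dispersions was fitted to all 9 libraries, so that the 3 groups share one estimate of the spread. Each comparison was a two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels are CPM, read counts scaled to the library's effective size on the TMM scale, given as mean and SD of 3 libraries. Standard errors of log2 fold changes were derived from the F statistics. Gene lists for pathways and cell types were written before the data were examined. Of 41 lists, 40 had at least 5 measured members and were tested with camera of limma 3.58.1, which asks whether a list's genes lie higher or lower than all other genes, on log2 CPM (prior count 2) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 40 lists. The sex-linked list, with 4 measured genes, was not tested. For every list the genes past the gene test were counted over all genes and adjusted over the list alone.

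The genes named were chosen by a rule fixed at the same stage. They are the 10 largest changes per direction among genes past the test whose groups do not overlap and whose mean log2 CPM is 0 or more, the 5 smallest p-values of a direction with fewer than 5 such genes, up to 4 members with the smallest p of each list described, and a fixed set of genes that includes Th, Slc6a3, Fkbp5, Sgk1, Cdkn1a, Pdk4, Per1, Fos, Bdnf and Mbp. Of the genes the rule names, 3 are not reported here, and no others take their places. Unnamed gene models were counted but not named. Genes outside the rule are said to be so where they appear.

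The edgeR, DESeq2 and camera steps were tested on simulated data drawn from the real means and library sizes with 200 changed genes. The changed genes were taken from those with a mean of 1 CPM or more, so the shares recovered do not cover genes below that level. For 1 day against ad libitum, edgeR recovered 11.9% of genes changed 1.5-fold, 44.8% of those changed 2-fold and 89.4% of those changed 4-fold among 20475 genes. For 1 week against ad libitum the shares were 16.4%, 58.2% and 93.9%, and for 1 week against 1 day they were 14.9%, 56.7% and 92.4%, each among 20474 genes. Among unchanged genes edgeR called 8, 6 and 12 in these comparisons, and DESeq2 called 39, 43 and 44. A fold change of 1.5 is therefore mostly missed at this number of libraries. Camera passed the 1 changed list and 0 of 20 unchanged lists in each comparison. The simulated genes were drawn independently, so this did not test camera on correlated genes.

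Alternatives set at that stage too were DESeq2 1.42.0, RLE size factors, no low-count filter, a filter of 1 CPM in at least 6 libraries, fits of only the 2 groups compared, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry, which tests whether a list's genes move one way on balance. A pseudocount alternative applied to normalized values only and was not needed. Leaving out both replicate 2 libraries of the fasted groups, and limma's voom with a quality weight per library, were added after the data were seen. For 1 week against 1 day the main fit did not pair the libraries. Pairing by replicate number entered the fits only through the block alternative. The deviations from the group means of libraries of equal number correlated at 0.154, 0.475 and 0.102. This pairing comes from the data and not from the labels, and it is weak, since 1 day replicate 1 was closer to 1 week replicate 3 (0.313) and 1 day replicate 3 to 1 week replicate 1 (0.320). The overlap of the comparisons that share the ad libitum libraries was set against 20 simulations of unchanged groups. Figures were drawn with matplotlib 3.10.9.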

Results

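Gene-level read counts were analysed in 9 substantia nigra libraries from sham-operated wild type mice, 3 from mice fed ad libitum, 3 from mice fasted for 1 day and 3 from mice kept on intermittent fasting for 1 week. Totals per library ranged from 38516394 to 45693865 counts in the ad libitum group, from 37732284 to 46522059 in the 1 day group and from 36109995 to 54248856 in the 1 week group. Th, which encodes the rate-limiting enzyme of dopamine synthesis, was present at 181 ± 23.9 CPM, counts scaled to library size (SD, n = 3), in the ad libitum group, 109 ± 46.4 CPM in the 1 day group and 208 ± 89.3 CPM in the 1 week group. Marker genes of neighbouring tissue differed in level between libraries. Slc17a7, a vesicular glutamate transporter of cortical neurons, was at 501 CPM in replicate 3 of the 1 week group and between 4.31 and 49.2 CPM in the others. Ttr, the main transcript of choroid plexus, was at 335 CPM in ad libitum replicate 3 and between 2.61 and 35.5 CPM in the others. Replicate 2 of the 1 day group and replicate 2 of the 1 week group stood apart from their groups. Their deviations from the group means correlated at r = 0.475 across 12799 genes, which are not independent replicates, and their estimated quality weights were 0.213 and 0.507, against 0.972 to 1.93 in the other 7 libraries.

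**Figure D1:**
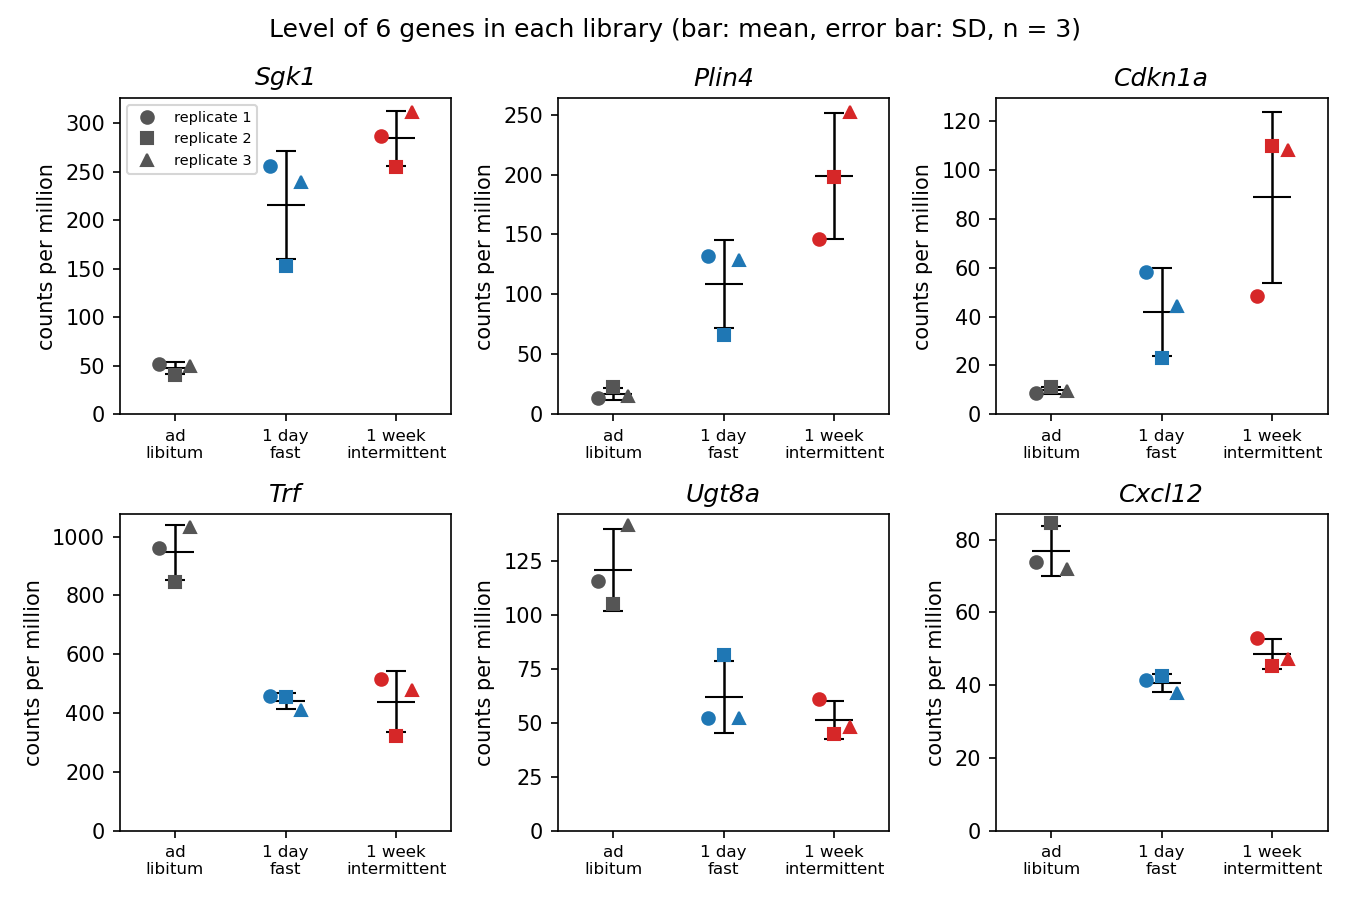
Level of Sgk1, Plin4, Cdkn1a, Trf, Ugt8a and Cxcl12 in CPM (y axis, from 0) in the 3 groups (x axis), with 1 point per library, the marker giving the replicate number, a horizontal bar for the mean and an error bar for the SD (n = 3). Sgk1 lies at a mean of 47.5 CPM in the ad libitum group, 216 CPM after 1 day and 285 CPM after 1 week, and Trf at 946, 441 and 438 CPM.

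The first comparison asked how the tissue responded to a single day without food. Sgk1 (ENSMUSG00000019970), a kinase gene induced by glucocorticoids, rose 4.55-fold, from 47.5 ± 5.99 to 216 ± 55.4 CPM (SD, n = 3; edgeR, log2 fold change 2.19, SE 0.19, adjusted p = 0.00468). Plin4 (ENSMUSG00000002831), which encodes a coat protein of lipid droplets, rose 6.33-fold, from 17.2 ± 5.08 to 109 ± 36.9 CPM (log2 fold change 2.66, SE 0.33, adjusted p = 0.0310). Arl4d, a small GTPase, rose 3.68-fold (SE 0.16 on the log2 scale) and Gabrr2, a GABA receptor subunit, rose 3.56-fold (SE 0.21). Cxcl12 (ENSMUSG00000061353), a chemokine gene, was the 1 gene that fell, from 76.9 ± 6.81 to 40.5 ± 2.49 CPM (log2 fold change -0.92, SE 0.11, adjusted p = 0.0160). In all, 12 genes changed after 1 day by edgeR's quasi-likelihood test, 11 higher and 1 lower, and 1904 genes had an unadjusted p below 0.05 where chance gives 1027. Arrdc2 rose 2.94-fold, Apold1, a gene of endothelial cells, 2.87-fold, Ddit4, an inhibitor of mTORC1 signalling, 2.57-fold, Plekhf1 2.18-fold and Net1, a guanine nucleotide exchange factor, 2.12-fold, with adjusted p between 0.0160 and 0.0478. Among the next lower genes by p, these did not pass: Unc5b, a netrin receptor (log2 fold change -0.92, adjusted p = 0.0609), S100a16 (-0.85, adjusted p = 0.0609) and Trf, which encodes transferrin (-1.10, adjusted p = 0.0634). DESeq2 called 187 genes, limma's voom with quality weights 93, edgeR on the 6 libraries alone 26, and edgeR without both libraries that stood apart 50. No gene passed edgeR's test without ad libitum replicate 1, 2 or 3, with adjusted p of the named genes up to 0.326, Sgk1 and Arl4d alone passed without 1 day replicate 1 or 3, and 22, 20 and 22 genes passed without 1 day replicate 2, 1 week replicate 1 and 1 week replicate 2. Plin4 missed the threshold without 1 week replicate 2 as well, and Ddit4 without 1 day replicate 2 and 1 week replicate 3.

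Of the 27 measured members of the list of genes induced through the glucocorticoid receptor 5 rose, namely Sgk1, Arl4d, Arrdc2, Plin4 and Ddit4, and 22 did not pass, while 19 rose and 0 fell adjusted over the list alone. Without ad libitum replicate 1, 2 or 3 none of the 5 passed over all genes. The list lay above other genes (median log2 fold change 0.72, camera adjusted p = 7.03e-19; adjusted p = 0.581 with an estimated correlation). For a move one way on balance, fry gave an adjusted p of 0.0911. Its mean difference from the ad libitum libraries was 1.21, 0.41 and 0.96 on the log2 scale in replicates 1, 2 and 3, the lowest being the library that stood apart. Fkbp5, a co-chaperone of that receptor, had a log2 fold change of 0.72 (SE 0.31, adjusted p = 0.532).

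Of 21 components and targets of insulin and FoxO signalling none passed over all genes, and 2 rose adjusted over the list alone. These were Klf15 (log2 fold change 0.73), a transcription factor of fasting metabolism, and Cdkn1a (2.10), a cell cycle inhibitor that is also on the glucocorticoid list. The FoxO list lay higher (median 0.19, camera adjusted p = 2.75e-04; adjusted p = 0.581 with an estimated correlation). Of 21 immediate early genes, which mark recent neuronal activity, none passed over all genes and 2 rose adjusted over the list alone, Btg2 (0.95) and Fos (1.76). That list's median was 0.44 (camera adjusted p = 0.0159; adjusted p = 0.778 with an estimated correlation). Without ad libitum replicate 3 and 1 day replicates 1 and 3 its adjusted p was 0.0775, 0.182 and 0.208, and its median was 0.17 without 1 day replicate 1, 0.74 without 1 day replicate 2 or both libraries that stood apart, and 0.73 with quality weights.

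Markers of oligodendrocytes and microglia and interferon-induced genes had negative medians after 1 day. No oligodendrocyte marker of 14 passed over all genes, and 7 fell adjusted over the list alone, among them Trf (-1.10), Mag (-0.58), a myelin adhesion protein, Ugt8a (-0.97), which makes the myelin lipid galactocerebroside, and Gjb1 (-0.66). The oligodendrocyte median was -0.31 (camera adjusted p = 1.96e-05; adjusted p = 0.581 with an estimated correlation), while Mbp, the myelin basic protein gene, was at -0.19 (SE 0.15, adjusted p = 0.645). Of 15 microglia markers 0 passed over all genes and 6 fell adjusted over the list alone, led by Fcrls (-1.04), with a median of -0.48 (camera adjusted p = 2.02e-06; adjusted p = 0.581 with an estimated correlation). Of 21 interferon-induced genes 0 passed over all genes and 5 fell adjusted over the list alone, namely Isg15 (-1.62), Gbp3 (-0.75), Ifit1 (-0.93), Bst2 (-1.26) and, named after its value was seen, Gbp2 (-0.95). The interferon median was -0.56 (camera adjusted p = 2.36e-07; adjusted p = 0.581 with an estimated correlation), and -0.33 among genes at 1 CPM in at least 6 libraries.

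The other 4 lists that lay lower after 1 day held no member past the test, over all genes or adjusted over the list alone. Nuclear genes of oxidative phosphorylation had a median of -0.11 (88 genes, camera adjusted p = 0.0135; adjusted p = 0.581 with an estimated correlation). Mitochondrially encoded genes had a median of -0.54 (13 genes, camera adjusted p = 0.0159; adjusted p = 0.717 with an estimated correlation). Dopaminergic neuron genes had a median of -0.27 (23 genes, camera adjusted p = 0.0244; adjusted p = 0.778 with an estimated correlation). Fibroblast and meninges markers had a median of -0.998 (12 genes, camera adjusted p = 0.00176; adjusted p = 0.717 with an estimated correlation). Without 1 day replicate 3 the adjusted p was 0.208 for oxidative phosphorylation, 0.757 (median -0.11) for dopaminergic neurons and 0.108 for fibroblasts, and the mitochondrial median was -1.03. The dopaminergic list also missed the threshold without ad libitum replicates 2 and 3 (adjusted p = 0.0817, and 0.121 with a median of -0.16) and had a median of -0.47 without 1 day replicate 1. The mitochondrial list missed it without ad libitum replicate 1 (adjusted p = 0.0596), 1 day replicate 1 (0.0982) and 1 day replicate 2 (0.248, median -0.22), and without both libraries that stood apart (0.158, median -0.22). The other 30 lists gave camera adjusted p between 0.0565 and 0.960. Median, mean and test differed in sign for the lists of ketone oxidation, endoplasmic reticulum chaperones, NRF2, the clock, neurotrophic factors and hypoxia, and other groupings of the same 6 libraries gave up to 21 lists past the threshold against 10 here.

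**Figure D2:**
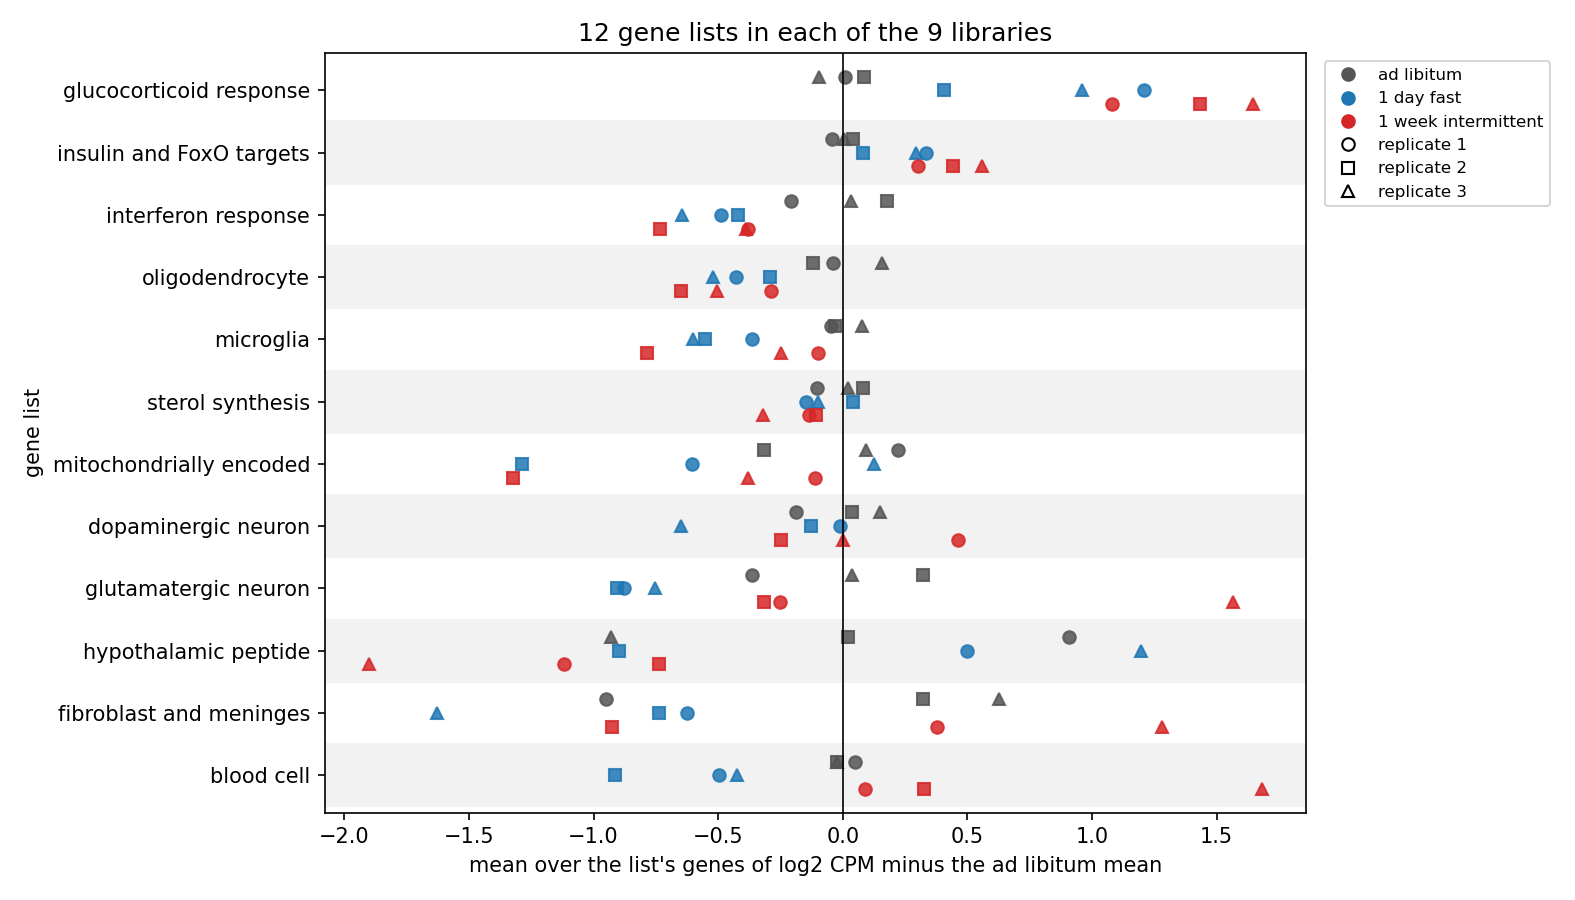
Mean over each list's genes of log2 CPM minus the ad libitum mean (x axis) for 12 gene lists (y axis), with 1 point per library, the colour giving the group and the marker the replicate number. For the glucocorticoid list the fasted libraries lie between 0.41 and 1.65 and the ad libitum libraries between -0.09 and 0.09. The blood cell and glutamatergic lists reach 1.68 and 1.57 in replicate 3 of the 1 week group.

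The second comparison asked what had changed after 1 week of the regimen. Plin4 rose 11.6-fold to 199 ± 52.8 CPM (SD, n = 3; edgeR, log2 fold change 3.53, SE 0.34, adjusted p = 0.00539), and Cdkn1a (ENSMUSG00000023067) rose 9.09-fold, from 9.77 ± 1.29 to 88.8 ± 34.9 CPM (log2 fold change 3.18, SE 0.41, adjusted p = 0.0242). Sgk1 rose 5.99-fold to 285 ± 28.0 CPM (log2 fold change 2.58, SE 0.20, adjusted p = 0.00154). Trf (ENSMUSG00000032554), the transferrin gene that oligodendrocytes express strongly, fell from 946 ± 94.0 to 438 ± 104 CPM (log2 fold change -1.11, SE 0.17, adjusted p = 0.0322). Ugt8a (ENSMUSG00000032854) fell from 121 ± 18.9 to 51.3 ± 8.69 CPM (-1.24, SE 0.20, adjusted p = 0.0381). By edgeR's quasi-likelihood test 63 genes changed after 1 week, 52 higher and 11 lower. Among the largest increases were Hif3a, a hypoxia-inducible factor subunit (log2 fold change 2.65, SE 0.30), Itgad, an integrin subunit (2.60, SE 0.38), Zbtb16, a transcription factor (2.48, SE 0.36), Map3k6 (2.39, SE 0.34), Gabrr2 (2.35, SE 0.21), Fam83d (2.29, SE 0.28) and Sult1a1, a sulfotransferase (2.24, SE 0.26). Besides Trf and Ugt8a, Sp7, a zinc finger transcription factor (-1.81, SE 0.28), Unc5b (-1.15, SE 0.14), Sox2ot (-1.11, SE 0.17), Eml1 (-1.09, SE 0.15), S100a16 (-0.83, SE 0.13), Creb5 (-0.68, SE 0.12) and Cxcl12 (-0.66, SE 0.11) fell, with adjusted p between 0.00957 and 0.0493. DESeq2 called 467 genes, limma's voom with quality weights 296 and edgeR on the 6 libraries alone 155. Without ad libitum replicate 1, 2 or 3 the count was 8, 11 or 9, and it was 22 and 17 without 1 week replicates 2 and 3, 30 and 121 without 1 day replicates 1 and 2, and 96 without 1 week replicate 1. Of the genes reported here that the naming rule gives for this comparison, Sgk1, Arl4d, Arrdc2 and Gabrr2 passed in all 9 fits that left out 1 library. Their adjusted p was up to 0.0299, 0.0299, 0.0440 and 0.0405. Plin4 lost its call without ad libitum replicate 3 (adjusted p = 0.0513). Fam83d lost its call without ad libitum replicates 1 and 2 (adjusted p up to 0.0947), Sult1a1 without replicates 1 and 3 (0.0690), and Hif3a and Klf15 without each ad libitum library (0.0920 and 0.0872). The 15 other calls among the genes the rule gives here ended without each ad libitum library and without 1 week replicate 3. Among these Unc5b and Eml1 reached adjusted p of 0.0833 and 0.142. Cdkn1a, Map3k6 and Pdk4 were lost without 1 week replicate 2 as well, with adjusted p up to 0.172, 0.187 and 0.169. Trf was lost without 1 day replicate 1 as well (0.185), and Itgad, Ugt8a, Sox2ot, S100a16, Cxcl12, Zbtb16, Sp7, Creb5 and Gjb6 without both of these (0.187, 0.200, 0.181, 0.180, 0.198, 0.193, 0.165, 0.249 and 0.188). In addition, the call of Zbtb16 ended without 1 day replicate 2, those of Sp7 and Gjb6 without 1 week replicate 1 and that of Creb5 without 1 day replicate 3.

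Of the 27 genes of the glucocorticoid list 15 rose after 1 week and 12 did not pass, and adjusted over the list alone 23 rose and 1 fell, Nr3c1, the gene of the receptor itself (-0.34), named after its value was seen. Without ad libitum replicates 1, 2 and 3 the count past the test over all genes was 4, 6 and 3, and 8 without 1 week replicate 2 or 3. Sgk1, Arl4d (log2 fold change 2.11), Arrdc2 (2.03) and Plin4 had the smallest p. The list's median log2 fold change was 1.16 (camera adjusted p = 1.64e-27; adjusted p = 0.251 with an estimated correlation), and fry gave an adjusted p of 0.0107. Its mean difference from the ad libitum libraries was 1.08, 1.44 and 1.65 in replicates 1, 2 and 3. Fkbp5 was 3.74-fold higher (log2 fold change 1.90, SE 0.31) and missed the threshold at an adjusted p of 0.05004. Pdk4, a kinase that limits glucose oxidation and is on this list and on that of fatty acid oxidation, rose 2.59-fold (1.37, SE 0.19, adjusted p = 0.0229), a call that ended without each ad libitum library and 1 week replicates 2 and 3 (adjusted p up to 0.169).

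Of 21 components and targets of insulin and FoxO signalling 2 rose, Klf15 (log2 fold change 1.15, adjusted p = 0.00957) and Cdkn1a, which is also on the glucocorticoid list. Adjusted over the list alone 5 rose, with Txnip (0.67), Trib1 (0.60) and Sesn1 (0.42) as the others. The list's median was 0.27 (camera adjusted p = 9.94e-07; adjusted p = 0.251 with an estimated correlation; fry adjusted p = 0.0159). Without each ad libitum library Klf15 and Cdkn1a did not pass (adjusted p up to 0.0872 and 0.172), nor did Cdkn1a without 1 week replicates 2 and 3. Genes of sterol synthesis lay lower, with 0 of 25 past the test and 2 lower adjusted over the list alone, Dhcr7 (-0.58) and Msmo1 (-0.46). Their median was -0.17 (camera adjusted p = 6.78e-04; adjusted p = 0.614 with an estimated correlation) and -0.11 without 1 week replicate 3. Of 17 genes of fatty acid synthesis 0 passed over all genes and 2 fell adjusted over the list alone, Elovl5 (-0.42) and Elovl6 (-0.50), which lengthen fatty acids and were named after their values were seen (median -0.17, camera adjusted p = 0.0270; adjusted p = 0.514 with an estimated correlation). That call ended without ad libitum replicates 2 and 3 (adjusted p = 0.0515 and 0.0716), 1 day replicate 1 (0.0530) and 1 week replicate 3 (0.0688, median -0.10).

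Among 14 oligodendrocyte markers 2 fell over all genes, Trf and Ugt8a, and 7 fell adjusted over the list alone, including Mag (-0.59) and Opalin (-1.35). Without each ad libitum library, 1 day replicate 1 or 1 week replicate 3 neither Trf nor Ugt8a passed (adjusted p up to 0.185 and 0.200), nor did Ugt8a without 1 week replicate 2. The median was -0.40 (camera adjusted p = 4.51e-06; adjusted p = 0.514 with an estimated correlation), and Mbp was at -0.06 (SE 0.15, adjusted p = 0.920). Of 21 interferon-induced genes 0 passed over all genes and 5 fell adjusted over the list alone, namely Gbp3 (-1.004), Isg15 (-1.21), Gbp2 (-0.96), Ifit1 (-0.80) and, named after its value was seen, Psmb9 (-0.73), with a median of -0.41 (camera adjusted p = 7.67e-08; adjusted p = 0.514 with an estimated correlation). The interferon median was -0.64 without 1 week replicate 1, -0.23 without 1 week replicate 2 or both libraries that stood apart and -0.27 among genes at 1 CPM in at least 6 libraries. Of 15 microglia markers 0 passed over all genes and 1 fell adjusted over the list alone, Fcrls (-1.03). The microglia median was -0.30 (camera adjusted p = 6.78e-04; adjusted p = 0.669 with an estimated correlation), -0.17 (adjusted p = 0.0387) without 1 week replicate 2 and -0.17 (adjusted p = 0.0552) without both libraries that stood apart. Of 12 astrocyte markers 1 rose, Gjb6, a connexin of astrocytes (0.78, SE 0.12, adjusted p = 0.0364), and the list did not pass (camera adjusted p = 0.162). The call of Gjb6 ended without each ad libitum library, 1 day replicate 1 and each 1 week library, with adjusted p up to 0.188.

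The other 5 lists past camera after 1 week held no member past the test, over all genes or adjusted over the list alone. Heat shock chaperones had a median of -0.20 (20 genes, camera adjusted p = 0.0107; adjusted p = 0.530 with an estimated correlation) and missed the threshold without 1 week replicate 1 (0.0873). Nuclear genes of oxidative phosphorylation had a median of -0.10 (camera adjusted p = 0.0170; adjusted p = 0.514 with an estimated correlation), which was not past the threshold without ad libitum replicate 2 (0.0586), without 1 week replicate 2 (0.0531, median -0.05) or with the stricter filter (0.0507), and the median was -0.05 (0.0182) without both libraries that stood apart. Mitochondrially encoded genes had a median of -0.63 (camera adjusted p = 0.0122; adjusted p = 0.811 with an estimated correlation) and of -0.30 without 1 week replicate 2 (adjusted p = 0.222) or both libraries that stood apart (0.171). Hypothalamic peptide genes had a median of -0.88 (10 genes, camera adjusted p = 0.0429; adjusted p = 0.669 with an estimated correlation). That call ended without ad libitum replicates 1 and 2 (adjusted p = 0.166 with a median of -0.55, and 0.0729), 1 day replicate 1 (0.0576) and 1 week replicates 1 and 3 (0.0873 and 0.257). It also ended with the stricter filter (0.231), with the 6 libraries alone (0.225, median -0.49) and with quality weights (0.0758). Blood cell genes had a median of 0.85 (5 genes, camera adjusted p = 0.0225; adjusted p = 0.675 with an estimated correlation), and of 0.16 without 1 week replicate 3 (adjusted p = 0.283). They also missed the threshold without ad libitum replicates 2 and 3 (0.0515 and 0.0534) and with the 6 libraries alone (0.0838). The other 28 lists gave camera adjusted p between 0.0827 and 0.967. Median, mean and test differed in sign for the lists of ketone oxidation, NRF2, NF-kB and activated microglia, and other groupings of the same 6 libraries gave up to 18 lists past the threshold against 12 here.

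Genes of the dopaminergic system and of Parkinson's disease were of interest because of the tissue. Th was at a log2 fold change of 0.20 (SE 0.36, adjusted p = 0.882) after 1 week and -0.73 (SE 0.36, adjusted p = 0.546) after 1 day by edgeR's test. Slc6a3, the dopamine transporter gene, was at 0.09 (SE 0.28, adjusted p = 0.939) and -0.49 (SE 0.28, adjusted p = 0.570). The values of Th and Slc6a3 after 1 week were -0.14 and -0.13 without 1 week replicate 1, and after 1 day that of Th was -1.14 without 1 day replicate 1 and that of Slc6a3 -0.26 without 1 day replicate 3. After 1 week Th was at 0.50 without 1 week replicate 2, 0.12 without ad libitum replicate 1 and 0.32 without ad libitum replicate 3, and Slc6a3 at 0.34 without 1 week replicate 2 and 0.21 without ad libitum replicate 3. None of the 23 dopaminergic and 18 Parkinson's disease genes passed the gene test in either comparison, over all genes or adjusted over the list alone. Bdnf, a neurotrophin gene, was at 0.27 (SE 0.19) in both, with adjusted p of 0.614 after 1 day and 0.657 after 1 week. Without ad libitum replicate 2 it was at 0.52 and 0.53, and without ad libitum replicate 3 at 0.12 in both. Of 27 genes of ketone and fatty acid oxidation 1 rose after 1 week, Pdk4, and 0 after 1 day, with camera adjusted p of 0.828 and 0.878. Autophagy and lysosome genes, with 0 of 38 past the gene test in either comparison, had medians of -0.06 after 1 day and -0.04 after 1 week (camera adjusted p = 0.460 and 0.595).

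The third comparison set 1 week directly against 1 day. Glucocorticoid-induced genes lay higher after 1 week, by a median of 0.40 on the log2 scale over 27 genes, 26 of them positive (camera adjusted p = 1.64e-08; adjusted p = 0.766 with an estimated correlation). For a move one way on balance, fry gave an adjusted p of 0.538. The libraries of both groups overlapped, with a mean difference from ad libitum of 1.21 in 1 day replicate 1 and 1.08 in 1 week replicate 1. Adjusted over the list alone 4 rose, Fkbp5 (1.18, SE 0.31), Zbtb16 (1.34, SE 0.34), Mertk (0.46), a phagocytic receptor tyrosine kinase, and Hif3a (1.06, SE 0.29). The median was 0.24 (adjusted p = 0.00479) without both libraries that stood apart and 0.23 with quality weights. Over all genes, no gene passed edgeR's test, with 1071 genes at an unadjusted p below 0.05 where chance gives 1027 and a smallest adjusted p of 0.853.

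DESeq2 called 3 genes between 1 week and 1 day, Tspan11 (log2 fold change 2.37, adjusted p = 0.00808), Apold1 (-0.79, adjusted p = 0.0401) and Gm9531, an unnamed gene model, and limma's voom called 0. By edgeR 3 genes passed without 1 week replicate 1 and 0 without any other library. Apold1 was at 12.7 ± 1.85 CPM (SD, n = 3) after 1 day and 7.34 ± 0.704 CPM after 1 week (edgeR, log2 fold change -0.79, SE 0.16, adjusted p = 0.853). Itpk1, an inositol phosphate kinase gene, was at 82.8 ± 9.11 and 115 ± 7.88 CPM (0.47, SE 0.11), Pdgfb, a growth factor gene, had a log2 fold change of 0.51 (SE 0.12) and Srarp 1.61 (SE 0.33). The lower genes with the smallest p after Apold1 were Zmynd10 (-1.20, SE 0.29), Wsb1 (-0.49, SE 0.13), Mex3a (-0.79, SE 0.21) and Fank1 (-0.82, SE 0.22), none of which passed.

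The other 8 lists past camera between 1 week and 1 day held no member past the test over all genes. The blood cell list was higher by a median of 1.39, with 5 of 5 members, all of hemoglobin or heme synthesis, higher adjusted over the list alone (camera adjusted p = 5.41e-06; adjusted p = 0.758 with an estimated correlation), and by 0.79 without 1 week replicate 3. The fibroblast and meninges list was higher by 1.25 (camera adjusted p = 7.40e-06; adjusted p = 0.792 with an estimated correlation), and by 0.67 without that library. The glutamatergic list was higher by 1.71 (camera adjusted p = 0.0112; adjusted p = 0.758 with an estimated correlation), by 0.52 without 1 week replicate 3, and not past the threshold without 1 day replicate 1 (0.124). Mural cell markers were higher by 0.31 (camera adjusted p = 0.0140; adjusted p = 0.835 with an estimated correlation), a call that ended without 1 day replicate 3 (0.215) and without 1 week replicate 1 (0.182). Dopaminergic genes were higher by 0.29 (camera adjusted p = 8.69e-04; adjusted p = 0.945 with an estimated correlation). Their call ended without 1 day replicate 3 (0.320, median 0.15) and without 1 week replicate 1 (0.418, median 0.12), and their median was 0.51 without both libraries that stood apart and 0.45 with quality weights. Hypothalamic peptide genes were lower, with a median of -1.67 (camera adjusted p = 6.86e-04; adjusted p = 0.758 with an estimated correlation), and not past the threshold without 1 day replicate 3 (0.0553). Ependymal markers had a median of -0.70 (camera adjusted p = 5.41e-05; adjusted p = 0.766 with an estimated correlation), -0.44 without 1 day replicate 3, -1.11 without 1 week replicate 2, -1.23 without both libraries that stood apart and -1.45 with quality weights. Sterol synthesis genes had a median of -0.14 (camera adjusted p = 0.0146; adjusted p = 0.898 with an estimated correlation). Their call ended without 1 day replicates 2 and 3 (0.180 with a median of -0.05, and 0.0553) and without 1 week replicate 3 (0.404, median -0.06), and their median was -0.21 without 1 day replicate 1 and -0.08 with quality weights. The other 31 lists gave camera adjusted p between 0.0519 and 0.912. Median, mean and test differed in sign for the lists of ketone oxidation, autophagy, heat shock, NRF2, immediate early genes, ribosomal proteins, cell division, interferon, oligodendrocyte precursors and astrocytes, and other groupings of the same 6 libraries gave up to 13 lists past the threshold against 9 here.

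**Figure D3:**
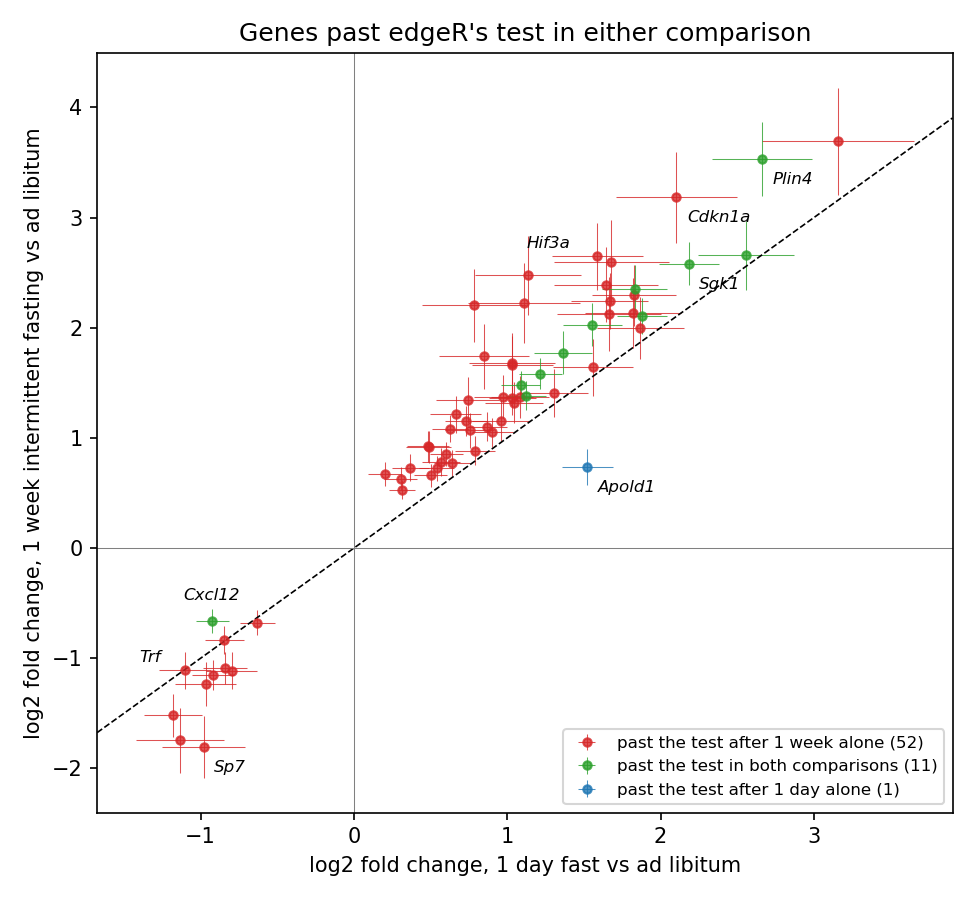
Log2 fold change after 1 day (x axis) and after 1 week (y axis), each against ad libitum, of the genes past edgeR's test in either comparison, with standard errors as error bars and the line of equal change dashed. All points lie in the quadrants of equal sign, 11 genes passed in both comparisons, and Apold1 was the 1 gene past the test after 1 day alone.

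The comparisons against ad libitum shared 11 genes past edgeR's test, 10 higher and 1 lower, and none in opposite directions. They included Plin4, Sgk1, Arl4d, Gabrr2, Arrdc2, Ddit4, Plekhf1 and Net1 on the higher side and Cxcl12 on the lower side. Independent lists of these lengths would share 0.0279 higher and 5.36e-04 lower genes, values that ignore the shared ad libitum libraries. Simulated unchanged groups, with every library drawn anew from the ad libitum means, shared 0.05 genes on average over 20 simulations. With no gene changed, few genes can pass in either comparison. The simulated count therefore cannot show how far shared controls raise the overlap. All 63 genes past the test after 1 week had the same sign after 1 day, and the fold change after 1 week was the larger in 52 of 52 higher genes and in 9 of 11 lower genes, which were selected for their size after 1 week. The log2 fold changes correlated at r = 0.608 across the genes tested, against a mean of 0.496 and a highest value of 0.544 in the simulations. Their covariance was 0.138 against a simulated mean of 0.0728, a difference of 0.0649. The 3 ad libitum libraries cannot be split into parts of at least 2, so part of the overlap may come from the shared controls. The simulations drew each library independently and so lack the deviation that both replicate 2 libraries of the fasted groups share. Part of the excess correlation and covariance may come from that deviation, which was not tested. Without both of these libraries the overlap was 32 genes. The overlap was 0 without ad libitum replicate 1, 2 or 3, 2 without 1 day replicate 1 or 3, 20 without 1 day replicate 2 and 18 without 1 week replicate 1.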

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

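The tests of cell mix, of a smaller oligodendrocyte share, of the pair of libraries that stood apart, of 1 day replicate 2 alone and of the time of day were chosen only after the result was seen.

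Replicate 2 of the 1 day group and replicate 2 of the 1 week group deviated from their groups together, with a correlation of 0.475 between their deviations over 12799 genes, a pattern found by comparing the libraries. Length of the transcripts is argued against as the cause, because the Spearman correlations of the deviations with length were 0.0801 and 0.0829. Another mix of cell types cannot be told apart from other causes, because of 5 cell type lists 0 deviated by over 2 standard errors in both libraries, either alike or in opposite directions. Mean deviations were -0.07 and -0.61 for microglia (SE 0.12 and 0.11) and 0.18 and -0.25 for oligodendrocytes (SE 0.10 and 0.07) in the 1 day and the 1 week library. GC content remains open, because the deviations correlated with it at -0.448 in the 1 day library and at -0.113 in the 1 week library, so whether it is a cause for both cannot be told apart from a cause in the 1 day library alone. No biological explanation was tested, since the labels give none that would join replicate 2 of both groups.

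Oligodendrocyte markers had medians of -0.31 after 1 day and -0.40 after 1 week. A smaller share of oligodendrocyte RNA would lower its markers alike if all came from these cells alone. They moved apart by more than their errors (Cochran's Q, a chi-square over the 14 genes, p = 6.11e-10 after 1 day and 6.43e-14 after 1 week, with Trf at -1.10 and Mbp at -0.19 after 1 day). This argues against an equal fall as the whole cause. A smaller share stays open where markers also come from other cells. Cochran's Q treats genes as independent, while their estimated correlation was 0.41 after 1 day. GC content and length are argued against, because the medians were -0.338 and -0.443 once their trends were removed. Without the pair of libraries that stood apart the medians were -0.389 and -0.276, so a part played by these libraries after 1 week cannot be told apart from the diet. A lower expression of some oligodendrocyte genes in fasted mice may account for the remainder and stays open, as an untested hypothesis.

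The direct test of 1 week against 1 day put 9 lists past camera's threshold, but 0 with an estimated correlation (smallest adjusted p = 0.758) and 0 with fry. The list of glucocorticoid-induced genes was higher by a median of 0.40, and low values in 1 day replicate 2 cannot be told apart from an effect of the regimen, because the median was 0.274 without that library and 0.235 without both libraries that stood apart. Sampling at another time of day is a candidate explanation that has the values it needs, since 7 of 21 clock genes had an unadjusted p below 0.05 between the groups. Hlf, Nr1d1 and Usp2 were higher and Cry1, Clock, Arntl and Nfil3 lower after 1 week. An effect of the regimen itself on clock genes would give such values too, so the count cannot tell these causes apart. The clock list's mean difference from ad libitum was -0.26 in 1 day replicate 2, against 0.01 and 0.12 in 1 day replicates 1 and 3. Its median between 1 week and 1 day was 0.158, and 0.0305 without both libraries that stood apart. Whether the count of clock genes rests on these libraries was not tested. Hlf and Clock were named after their values were seen, and Per1 belongs to both lists. A response that builds up over repeated fasts stays open and was not tested.

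The other lists past camera, with adjusted p of 0.758 to 0.945 with an estimated correlation, were sterol synthesis (median -0.14), dopaminergic neurons (0.29), glutamatergic neurons (1.71), hypothalamic peptides (-1.67), mural cells (0.31), fibroblasts and meninges (1.25), ependymal cells (-0.70) and blood cells (1.39). Calls ended without 1 day replicate 1 for glutamatergic neurons (adjusted p = 0.124), without 1 day replicate 2 for sterol synthesis (0.180, median -0.05), and without 1 day replicate 3 for sterol synthesis and hypothalamic peptides (0.0553 each), dopaminergic neurons (0.320, median 0.15) and mural cells (0.215). They also ended without 1 week replicate 1 for dopaminergic neurons (0.418, median 0.12) and mural cells (0.182), and without 1 week replicate 3 for sterol synthesis (0.404, median -0.06). Without 1 week replicate 3 the medians were 0.52 for glutamatergic neurons, 0.67 for fibroblasts and 0.79 for blood cells. The ependymal median was -0.44 without 1 day replicate 3 and -1.11 without 1 week replicate 2, and that of sterol synthesis -0.21 without 1 day replicate 1. All libraries of 1 group lay above the ad libitum mean and all of the other below it for Ppp1r10, Mex3a and Nfil3. Their mean log2 CPM after 1 week minus that after 1 day was 0.364, -0.788 and -0.390, and this opposition was itself not tested.

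Of the genes outside the gene tests, 14 had no count in the ad libitum libraries and counts in a fasted library, and were named after their values were seen. Prl, the pituitary hormone prolactin, reached 75 counts in 1 week replicate 2. The other 13 are pseudogenes, gene models and Zfp969, with their highest counts in 1 day replicate 2 or 1 week replicate 2. They had at most 5 counts in the other fasted libraries, so they mark these 2 libraries and not the fasted groups. The highest counts were 946 for Gm12918, 3087 for Gm5537, 140 for Rps13-ps2, 230 for Rpl10-ps1, 492 for Rpl19-ps11, 2479 for Rps6-ps4 and 1175 for Gm12435. For Gm11632 the highest count was 135, for Zfp969 54, for Gm28439 8773, for Gm49369 2776, for Nudc-ps1 110 and for Gm5512 59.

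Other divisions of the same 6 libraries into 3 and 3 number 10 with the real one, which is too few for a share under 0.05. The real counts of genes were 12 after 1 day, 63 after 1 week and 0 for 1 week against 1 day, and the highest of the other divisions were 0, 2 and 1. As large a count came from 1, 1 and 10 of the 10 divisions. For gene lists the real counts were 10, 12 and 9, the highest others 21, 18 and 13, and 3, 4 and 4 divisions gave as many. Pairs of 1 week and 1 day libraries by replicate number are weak outside number 2, with correlations of deviations of 0.154, 0.475 and 0.102 for numbers 1, 2 and 3. The real division parts all 3 of these pairs. The other 3 divisions that do so gave 8, 13 and 8 lists and 0 genes, while those that part 1 pair gave 2 to 12 lists and at most 1 gene.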

How the results depend on the processing

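Leaving out both replicate 2 libraries of the fasted groups and voom with quality weights were chosen only after the result was seen. Of 34 named gene calls, RLE size factors, no filter, DESeq2 and voom kept 34, the fits of the groups compared alone 33, the stricter filter 32 and the fit without both replicate 2 libraries 23. All 34 gene calls and 31 list calls kept their sign with each library left out, and 4 and 15 of them stayed past the threshold each time. Where a library is left out its group keeps 2. Whether fewer libraries account for the lost calls was not tested, and some of these fits gave more genes. At this depth the lowest mean of a deposited gene was 9.89 counts. DESeq2 gives no list test, and a pseudocount does not apply to counts.

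For 1 day against ad libitum, 26 genes passed with the groups compared alone, 50 without both replicate 2 libraries, 93 with voom and 187 with DESeq2, and 0 to 22 with 1 library left out, against 12. For 1 week the counts were 155 with the groups compared alone, 296 with voom, 467 with DESeq2 and 8 to 121 with 1 library left out, against 63. For 1 week against 1 day DESeq2 gave 3, edgeR 0 to 3 with 1 library left out and voom 0, against 0 with 1071 genes at an unadjusted p below 0.05. The overlap of 11 was 19 with the groups compared alone, 32 without both replicate 2 libraries, 80 with voom, 139 with DESeq2 and 0 to 20 with 1 library left out. As a block, the replicate number kept 14 of the 34 gene calls and gave 2 and 32 genes for 1 day and 1 week and an overlap of 2, but the numbers do not pair the ad libitum libraries with the fasted ones, with residual correlations of -0.305 to -0.185 with 1 day and -0.0437 to 0.248 with 1 week for equal numbers. Of all 9 libraries, 3 were closest to one of their own number. For 1 week against 1 day, where the pairing by number is weak, the block gave 0 genes and 9 lists and changed no call.

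The 10 lists past camera after 1 day were 17 with voom, 6 to 17 with 1 library left out, 0 with an estimated correlation and 0 with fry. The 12 after 1 week were 8 to 17 with 1 library left out, 0 with an estimated correlation and 2 with fry. The 9 between 1 week and 1 day were 5 to 11, 0 and 0. An estimated correlation changes both the variance and the degrees of freedom of camera's test, and which of these ended the calls was not tested, nor was the cause with fry.

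For lists, a turn below is one of the direction that camera gives, and the values are medians, which need not change sign with it. Without both replicate 2 libraries the sign turned for Mbp after 1 week (0.0452) and, for 1 week against 1 day, for Ugt8a (0.0732) and Aspa (0.0361). Camera's direction turned there for the clock (0.0305, against 0.158), interferon (0.215, against 0.00845) and oligodendrocyte (0.105, against -0.0284) lists, and with voom for the interferon (0.0998) and oligodendrocyte (0.0707) lists. Without both replicate 2 libraries the interferon list passed in the turned direction (camera adjusted p = 0.0468), which it did not with all libraries. Camera's direction for ketone oxidation after 1 day turned with the groups compared alone (-8.12e-04, against -0.00496), and the sign of Bdnf for 1 week against 1 day with RLE (-0.00323), the groups compared alone (-0.00302) and DESeq2 (-0.00334). The cause was not tested.

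With 1 library left out, camera's direction turned after 1 day for the ketone oxidation list (-0.0593 to 0.0425) and the clock list (3.18e-04 to 0.0942). After 1 week it turned for the lists of immediate early genes (-0.0875 to 0.525) and dopaminergic neurons (-0.0975 to 0.231), and the sign turned for Nr4a2 (-0.0233 to 0.277), Th (-0.138 to 0.496), Slc6a3 (-0.131 to 0.336) and Mbp (-0.136 to 0.0670). For 1 week against 1 day camera's direction turned for the lists of autophagy (-0.0264 to 0.0489), immediate early genes (-0.396 to 0.244), Parkinson disease (-0.0187 to 0.0722), interferon (-0.0770 to 0.0971), oligodendrocytes (-0.125 to 0.0497), astrocytes (-0.0629 to 0.0571) and microglia (-0.00171 to 0.429), and the sign for Bdnf (-0.0933 to 0.0677). The median alone crossed 0, with camera's direction kept, for sterol synthesis after 1 day (-0.137 to 0.0318), for ketone oxidation (-0.0324 to 0.0234), autophagy (-0.0684 to 8.07e-04) and Parkinson disease (-0.106 to 0.0111) after 1 week, and for ketone oxidation between 1 week and 1 day (-0.0316 to 0.0569). None of these was past the threshold with all libraries, and the cause was not tested.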

Other observations

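The tissue genes and list means below were chosen only after the result was seen. Genes of the circadian clock moved in opposite directions within 1 list, and camera gave no call for the 21 genes (adjusted p = 0.709 after 1 day and 0.338 after 1 week). Adjusted over the list alone 4 genes differed after 1 day. Cry1, a repressor of the clock, rose from 15.1 ± 1.10 to 26.5 ± 1.02 CPM (SD, n = 3; edgeR, log2 fold change 0.81, SE 0.13; adjusted p 0.0766 over all genes, as for the following). Nr1d1, the gene of REV-ERB alpha, fell from 84.2 ± 2.67 to 35.6 ± 15.8 CPM (-1.24, SE 0.30; adjusted p 0.325). Dbp fell from 67.7 ± 0.905 to 33.1 ± 14.4 CPM (-1.03, SE 0.30; adjusted p 0.418), and Bhlhe40 from 67.2 ± 1.69 to 50.8 ± 5.76 CPM (-0.40, SE 0.10; adjusted p 0.325). After 1 week 3 genes differed over the list alone: Per1 rose to 105 ± 6.94 CPM from 54.5 ± 4.63 CPM (0.94, SE 0.21; adjusted p 0.122), Usp2 rose (0.65, SE 0.15; adjusted p 0.124) and Bhlhe40 fell (-0.36, SE 0.10; adjusted p 0.213). Between 1 week and 1 day Usp2 was higher (0.55) and Cry1 (-0.48) and Arntl (-0.47) lower over the list alone, with adjusted p of 0.853 over all genes. Sampling at another time of day was not tested for the comparisons with ad libitum. For clock genes and the glucocorticoid list it cannot be told apart from the diet there.

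Genes typical of tissue other than the substantia nigra differed in level between the libraries, and were named after their values were seen. Whether the pieces of tissue taken were the cause was not tested. Growth hormone (Gh) had 807 counts in 1 week replicate 2, 277 in 1 week replicate 3 and at most 4 in the other 7 libraries. Hoxb3, a gene of the hindbrain and spinal cord, had 335 counts in 1 week replicate 3, 80 in ad libitum replicate 3 and at most 8 elsewhere, and Hoxb5 had 256 and 14. Pmch, the hypothalamic gene of melanin-concentrating hormone, ranged from 0.254 to 43.7 CPM and Hcrt, the orexin gene, from 0 to 9.42 CPM. Slc17a7 at 501 CPM, Col1a2 at 76.97 CPM and Hba-a1 at 370 CPM were all in 1 week replicate 3. Rn18s-rs5, a ribosomal RNA gene, took 1.21%, 8.72% and 0.235% of the counts of ad libitum replicates 1, 2 and 3, and 0.0200% to 0.311% in the fasted libraries. Lars2 was at 1561, 11414 and 328 CPM in the same ad libitum libraries and at 34.9 to 372 CPM in the fasted ones. Both were higher in every ad libitum library than in every 1 week library. Whether the preparation of the RNA differed between the groups was not tested, and it cannot be told apart from the diet.

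Of the 40 lists tested 22 passed camera in no comparison, among them autophagy, glycolysis, synaptic genes, cytosolic ribosomal proteins and neurotrophic factors. Choroid plexus genes lay at 1.55 in ad libitum replicate 3 against the ad libitum mean, at -1.22 and -0.33 in the other ad libitum libraries and at -1.40 to -0.09 in the fasted libraries. Mitochondrially encoded genes lay at -1.29 and -1.32 in the pair of replicate 2 libraries that stood apart, against -0.60 to 0.22 in the other 7. Counts of at least 100 in both of these libraries and 0 in the other 7 were found for 7 genes, and no other pair of the 36 had any.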
